A study of Homo sapiens with 22 samples.

How the data were processed

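Gene expression was measured by RNA sequencing in 12 libraries of HEK293 cells, 2 in each of 6 groups: WT, VPR sgHBB, p300 sgHBB, p300 D1399Y sgHBB, VPRP sgHBB and VPRP non-target. Per the labels' protocols, dox was given over 48 hours to induce the fusions, and cells were sorted by fluorescent markers before RNA was taken. Another 10 samples of H3K27ac ChIP-seq belong to the series and were not analysed here; the labels of 2 of them conflict, so these stay in no group.

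The deposited table holds whole-number counts of reads per gene, not normalized, for 48162 gene IDs. Per the submitters' processing notes, the tools named include STAR 2.5, HTSeq 0.6.1, DESeq2 1.24.0, BWA and deepTools, and the build hg19; the notes give them no role or order, and the annotation release and the strand setting of the counting are not given in the sources used here. Reads of overlapping, antisense or near-identical genes can therefore not be assigned with certainty, which concerns the FRG2, ALPG, PRR20G, GOLGA6, GOLGA8, MAGEA, HBA, HBG and histone genes named here. Gene symbols were taken from a table of gene names and matched 33626 IDs; the 14536 IDs without a symbol took 0.77% to 0.9% of the counts. A table of the GRCh38.p14 assembly served only for older names, so no coordinates are given. Each of the 12 count columns was assigned by its own name.

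Total counts ran from 14894558 to 17479523 (a ratio of 1.17), and 13610 to 14776 genes reached 1 CPM or more. A count of 0 allows up to 3 counts. Replicate libraries differed by more than sampling noise: the variance between the 2 libraries of a group was 2.86 (VPRP non-target) to 13.67 (VPR) times the Poisson value over genes with a mean count of at least 50.

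Counts were analysed in R 4.3.3 with edgeR 4.0.16 (limma 3.58.1). Genes were filtered with filterByExpr by group (minimum count 10, minimum total 15), which left 16694, and scaled with TMM factors. A model with a mean for each of the 6 groups was fitted to all 12 libraries with the quasi-likelihood method, and 11 comparisons were tested with Benjamini-Hochberg adjustment at 0.05. The SE of a log2 fold change was taken as its size over the square root of the quasi-F statistic. CPM values were scaled by the same factors. Against a group with 0 counts a fold is given as a limit from 3 counts over the group; with 1 to 3 counts the ratio of summed counts is given with its exact 95% binomial interval, which covers counting error only. With both groups at or under 3 counts no fold is given.

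Before the data were examined, the groups, the tests, 21 gene lists and the rule for named genes were fixed. The rule takes HBB, the other globin genes, EP300 and RELA, then the 8 largest changes each way (VPRP against WT, VPRP against non-target, VPRP against VPR, p300 against p300 D1399Y) or the 4 largest (other comparisons) among genes with adjusted p under 0.05, at least 2-fold, a mean log2 CPM of at least 1, both libraries of the groups separated (not required for the interaction) and a symbol, and up to 4 members of each described list. Of 345 list members 336 matched an ID. The 17 lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, in 187 tests adjusted together. Results for 1 gene that the rule names, and 1 test built on it, were left out. The gene sets followed across comparisons and 6 gene families defined by symbol were chosen after values had been seen.

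The reads carried no molecular identifiers, so intervals and floors do not cover amplification. The steps were tested on simulated data with 200 changed genes, and shares are of those that passed the filter (65, 62 and 65 genes at the 3 sizes with edgeR). For VPRP sgHBB against WT, with 15997 genes tested, edgeR recovered 69.2%, 77.4% and 92.3% of genes changed 1.5-fold, 2-fold and 4-fold, with 11 false calls. For the interaction the shares were 43.1%, 58.1% and 80%, with 3 false calls. Only the VPRP sgHBB libraries were changed in the simulation, up or down at random. The measured data had 59.1% of genes called in VPRP sgHBB against WT, and the simulation does not test scaling or false calls at such a share. Alternatives were DESeq2 1.42.0, RLE and upper-quartile factors, no low-count filter, a stricter filter (1 CPM in at least 2 libraries), fits of the compared groups alone, a replicate block, each of the 12 libraries left out in turn and, for lists, an estimated correlation and fry. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.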

Results

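RNA sequencing was done on HEK293 cells, a line derived from human embryonic kidney, that carried dox-inducible fusions of catalytically dead Cas9 (dCas9), a protein that binds DNA at the site of a guide RNA without cutting it. The fusions were VPR (the activation domains VP64, p65 and Rta), p300 (an acetyltransferase, encoded by EP300), p300 D1399Y (p300 with a substitution that impairs its catalysis) and VPRP (VPR joined to p300). A guide against HBB, the beta-globin gene, went with each fusion, and VPRP was also used with a non-targeting guide. The WT group held a guide and no dCas9 fusion; which guide is not stated in the labels, so comparisons with WT may also differ in the guide. Cells were induced for 48 hours and sorted for the fluorescent markers, and each of the 6 groups had 2 libraries, which the series describes as biological replicates. Total counts ran from 14894558 to 17479523 per library, and 16694 genes passed the count filter. Levels are in CPM, counts scaled to library size, with the SD of the 2 libraries (n = 2). Adjusted p-values come from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment unless another test is named. A fold against a group with 0 counts is a lower limit, computed from a floor of 3 counts over the group; intervals and floors cover counting error only.

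The first question was how strongly each fusion raised its target, HBB (ENSG00000244734). HBB reached 1556 ± 250 CPM with VPRP and the HBB guide, 187 ± 2.67 CPM with p300, 80.4 ± 20.6 CPM with VPR and 79.1 ± 4.23 CPM with p300 D1399Y. No read was counted in the WT or the VPRP non-target libraries, which allows up to 0.0989 and 0.0869 CPM over each group. HBB was therefore at least 15600-fold higher than in WT with VPRP (adjusted p = 7.5e-30), at least 1890-fold with p300 (adjusted p = 2.51e-25), at least 807-fold with VPR (adjusted p = 7.75e-22) and at least 797-fold with p300 D1399Y (adjusted p = 8.58e-22). Against the non-targeting guide the VPRP value was at least 17700-fold higher (adjusted p = 4.49e-30). Between fusions, VPRP gave 19.4 times the HBB of VPR (log2 4.28, SE 0.114, adjusted p = 2.21e-24) and 8.31 times that of p300 (log2 3.06, SE 0.107, adjusted p = 1.68e-20). VPR gave less than p300 (log2 -1.22, SE 0.107, adjusted p = 1.02e-10), and p300 gave 2.37 times the HBB of p300 D1399Y (log2 SE 0.107, adjusted p = 1.14e-10). The SE rests on a spread shared by all groups, and the 2 VPR libraries differed more. Without VPR replicate 2 or 1 the log2 value was -1.50 or -0.98 for VPR against p300. For VPRP against VPR it was 4.56 or 4.03. The limits against WT rest on the floor: on the log2 scale the VPRP limit was 13.93, and it was 12.95 without WT replicate 1 and 12.90 without WT replicate 2. In the same order the limit was 9.91 and 9.86 for p300, 8.68 and 8.63 for VPR and 8.67 and 8.61 for p300 D1399Y, and against the non-targeting guide it was 13.20 and 13.06 without its replicate 1 or 2.

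**Figure D1:**
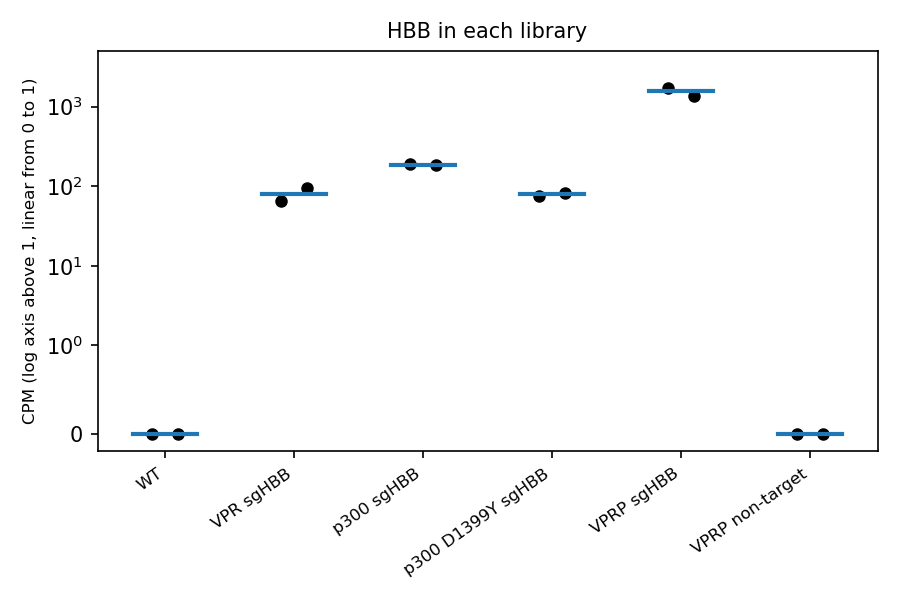
HBB level in CPM (log axis above 1, linear from 0 to 1) in each of the 12 libraries by group; points are libraries and bars are means of 2. The VPRP sgHBB libraries lie at a mean of 1556 CPM, above the other groups, and the WT and VPRP non-target libraries lie at 0.

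VPRP was also set against its parts. Its mean of 1556 CPM was 5.82 times the sum of the VPR and p300 means, 267.5 CPM, and the lower VPRP library was 4.86 times the sum of the highest VPR and highest p300 libraries. VPR, unlike VPRP sgHBB and p300, lies on the WT side of the MAGEA10 split described below. EP300 reads also differ, with an excess over WT in VPRP sgHBB of 26.35% of that in p300. The amounts of the fusion proteins were not measured here, so such differences cannot be told apart from joining the parts. On the multiplicative scale the order turns: the change from adding the VPR part was smaller with p300 present than without it, with an interaction of at most -6.61 on the log2 scale (at least 97.6-fold, adjusted p = 2.45e-12). WT had 0 HBB counts, so this too is a limit, and it was -5.64 without WT replicate 1 and -5.58 without WT replicate 2. A product of the single effects would have needed at least 807 times the HBB of p300. With WT at 0 counts a negative value was thus close to fixed in advance. It says little about how the 2 parts act together. HBE1, embryonic epsilon-globin in the same cluster, was higher than in WT with p300 (count ratio 25.8, 95% interval 8.53 to 128), VPRP sgHBB (25.1, 8.3 to 124) and VPRP non-target (26.1, 8.64 to 129). It was at 2.56 ± 0.451 CPM with p300, 2.49 ± 0.165 with VPRP and the HBB guide and 2.58 ± 0.0376 with VPRP and the non-targeting guide, against 0.0346 ± 0.0489 with p300 D1399Y. The HBE1 count ratio of p300 to p300 D1399Y was 81.0 (95% interval 14.2 to 3240), and the HBB and non-targeting guides differed by log2 -0.05 (SE 0.38, adjusted p = 0.939). HBG2 was at 0.63 ± 0.0316 CPM with VPRP and 0.197 ± 0.0879 in WT, with no call (adjusted p = 0.115). In the alpha-globin cluster, HBA2, which has a near-identical copy, had a count ratio to WT of 24.6 (95% interval 4.07 to 1010) with VPRP non-target and 20.9 (3.39 to 860) with VPRP sgHBB, and the second call was lost without WT replicate 2 (adjusted p = 0.0541). HBQ1, theta-globin, was lower than in WT with VPRP non-target (log2 -0.92, SE 0.149, adjusted p = 2.53e-06).

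Reads of EP300 (ENSG00000100393) can come from the cells' own gene and from the construct, which the counts do not separate. EP300 was at 107 ± 5.4 CPM in WT and 98.7 ± 17.6 with VPR, and it rose to 1124 ± 11.2 with p300, 1172 ± 9.92 with VPRP non-target, 375 ± 33.3 with VPRP sgHBB and 195 ± 1.19 with p300 D1399Y. The excess over WT in p300 D1399Y was 8.66% of that in p300, and the excess in VPRP sgHBB was 25.2% of that in VPRP non-target. Comparisons of these fusions therefore also compare different amounts of EP300 reads. A further difference ran across the groups. MAGEA10, a cancer-testis antigen, was at 9.46 ± 0.163 CPM in WT, 25.9 ± 1.47 with VPR and 32.1 ± 0.0315 with VPRP non-target, and at 0 with p300, 0.0692 ± 0.0978 with p300 D1399Y and 0.213 ± 0.0673 with VPRP sgHBB. TWIST2, a transcription factor, had the opposite split, with 0 counts in WT and VPR and 3.52 ± 0.836 CPM with VPRP sgHBB. This is named below as the MAGEA10 split. It is crossed by p300, p300 D1399Y and VPRP sgHBB against WT, by VPRP sgHBB against VPRP non-target, by VPRP sgHBB against VPR and by VPR against p300; the other 4 pairs each lie on the same side of it.

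**Figure D2:**
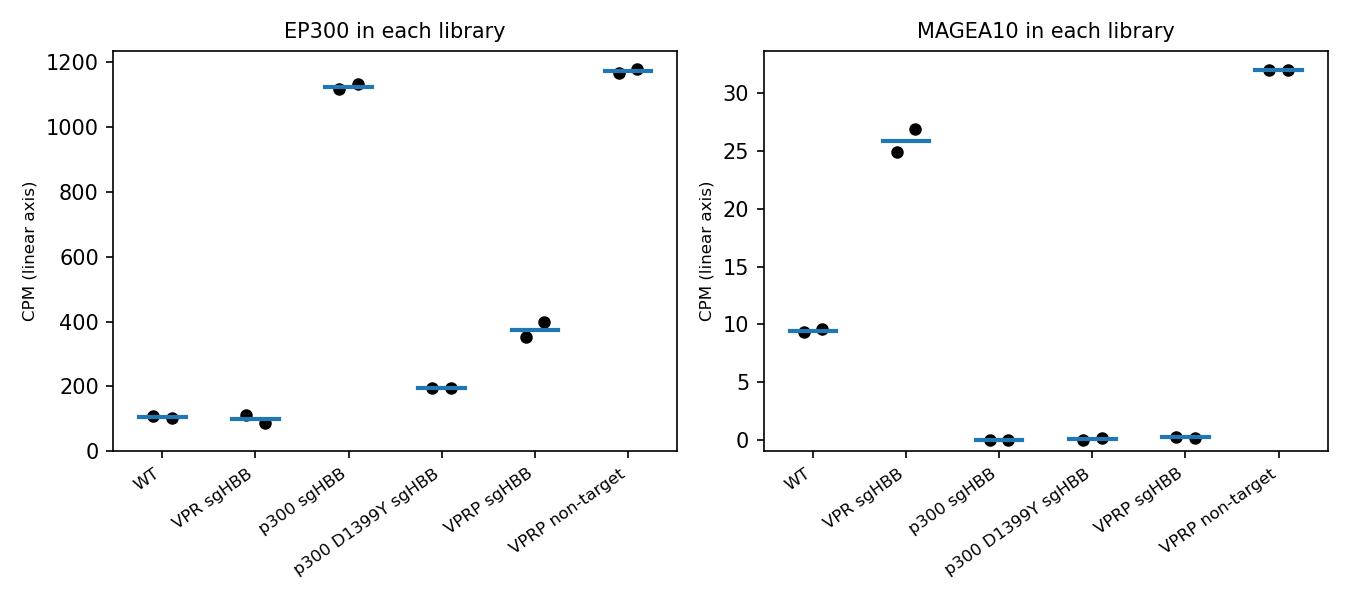
EP300 and MAGEA10 levels in CPM (linear axes) in each of the 12 libraries by group; points are libraries and bars are means of 2. EP300 is highest with p300 (1124) and VPRP non-target (1172), and MAGEA10 is near 0 with p300, p300 D1399Y and VPRP sgHBB.

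VPRP with the HBB guide was compared with WT to find what changed beside HBB. RFPL4A, FRG2B and FRG2 had no read in WT and were at least 374-fold, 254-fold and 123-fold higher. MPO, the myeloperoxidase of neutrophils, was at least 49.9-fold higher, FGF23, a phosphate-regulating hormone, at least 64.1-fold, ALPG, an alkaline phosphatase, at least 127-fold, and PRR20G at least 72.6-fold. FRG2B, FRG2, ALPG and PRR20G have near-identical relatives, so the split of reads between copies is uncertain. The largest falls were in MAGEA10 (43.6-fold), LINC00470 (33.0-fold), GDA (32.9-fold), WDR72 (30.5-fold), TSSC2 (24.3-fold), GABRA3 (24.0-fold), FLI1 (23.2-fold) and MKRN3 (18.2-fold), and this comparison crosses the MAGEA10 split. Of 18 p53 targets, 16 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 6.44e-10, and adjusted p = 0.0134 with an estimated correlation). CDKN1A, a cell cycle inhibitor, rose by log2 2.46 (SE 0.078), FDXR by 1.77 and SESN1 by 1.43. Of 15 replication-dependent histone genes, 12 rose, among them H1-2 (log2 2.47) and H2BC5 (2.38), but the set call did not hold (adjusted p = 0.121 with an estimated correlation). Of 17 immediate early genes, 10 rose and 4 fell, with no set call (camera adjusted p = 0.0768). Among them EGR1 rose by log2 5.15 (SE 0.142) while MYC fell by 1.90. In all, 5187 genes were higher and 4681 lower, 2405 and 942 of them at least 2-fold.

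VPR was compared with WT. Beside HBB, MPO was at least 51.6-fold higher and EVPL, a component of the epidermal cornified envelope, was 38.2-fold higher (log2 5.25, SE 0.364, adjusted p = 8.13e-13). DDIT3, a stress-response transcription factor, was 3.02-fold lower, ZNF256 2.97-fold and FZD10, a Wnt receptor, 2.89-fold. ALPG (adjusted p = 0.0197) and FTCD (3.32-fold lower, adjusted p = 0.0192) were also called, but ALPG lost its call without VPR replicate 2 (adjusted p = 0.384) or either WT library (0.099 and 0.109), and FTCD without VPR replicate 2 (0.231) or WT replicate 2 (0.237). Among the p53 targets (18 tested), 15 rose and 1 fell (15 and 1 adjusted over the list alone; camera adjusted p = 1.37e-15, and adjusted p = 0.00846 with an estimated correlation), with CDKN1A up by log2 1.32 and BTG2 by 0.76. RELA, the gene of p65, was lower by log2 -0.27 (SE 0.078, adjusted p = 0.0107), a call lost without VPR replicate 2 (adjusted p = 0.126) or WT replicate 2 (0.0903). The comparison gave 2307 higher and 1913 lower genes, 404 and 112 of them at least 2-fold. The larger share of higher genes turned with the scaling, to 2074 higher and 2153 lower with RLE factors. The 4220 changed genes became 2746 without VPR replicate 2, 2752 without WT replicate 1 and 2548 without WT replicate 2.

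With p300, RFPL4A was at least 67.4-fold, TWIST2 at least 40.7-fold and FRG2B at least 37.9-fold higher than in WT. MAGEA10 was at least 105-fold lower, TSSC2 37.3-fold lower, and the count ratio of LINC00470 was 0.0174 (95% interval 0.00355 to 0.0518); the comparison crosses the MAGEA10 split. Of 17 immediate early genes, 10 rose and 2 fell (10 and 2 adjusted over the list alone; camera adjusted p = 1.79e-05, and adjusted p = 0.032 with an estimated correlation), led by EGR1 (log2 4.76) and FOS (log2 3.78). Of 15 replication-dependent histone genes, 12 rose (12 adjusted over the list alone; camera adjusted p = 1.01e-09, and adjusted p = 0.0414 with an estimated correlation), among them H4C8 (log2 3.93) and H2AC6 (log2 2.50). Of 18 p53 targets, 13 rose and 1 fell (14 and 1 adjusted over the list alone; camera adjusted p = 2.69e-06, and adjusted p = 0.0304 with an estimated correlation). Genes higher numbered 4084 and genes lower 3610, with 1468 and 464 at least 2-fold.

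The catalytically impaired p300 D1399Y was compared with WT, again across the MAGEA10 split. MPO was at least 52.2-fold, TWIST2 at least 43.6-fold and ALPG at least 13.7-fold higher. MAGEA10 had a count ratio of 0.00666 (95% interval 0.000802 to 0.0243), WDR72 of 0.0112 (0.00229 to 0.0331) and ZNF681 of 0.0147 (0.00176 to 0.0542), and TSSC2 was 58.4-fold lower. In the p53 list of 18 targets, 16 rose and 1 fell (16 and 1 adjusted over the list alone; camera adjusted p = 1.91e-36, and adjusted p = 0.00166 with an estimated correlation), with GDF15 up by log2 3.88 and CDKN1A by 2.19. Genes of the integrated stress and unfolded protein responses were 4 higher and 11 lower of 23 (4 and 11 adjusted over the list alone; camera adjusted p = 0.000535), a call lost with an estimated correlation (adjusted p = 0.209). In all, 2626 genes were higher and 2419 lower, 683 and 322 of them at least 2-fold, but with RLE factors 2466 were higher and 2626 lower.

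VPRP with the non-targeting guide was compared with WT, whose guide is not stated, and both groups lie on the same side of the MAGEA10 split. RFPL4A was at least 821-fold, FRG2B at least 591-fold, FRG2 at least 178-fold and PRR20G at least 163-fold higher. MPO was at least 32.8-fold higher here too, without the HBB guide. NUPR1, a stress-response gene, was 11.4-fold lower, TSC22D3, a glucocorticoid-induced gene, 9.78-fold and SLC6A9, a glycine transporter, 7.34-fold. Of 15 replication-dependent histone genes, 14 rose (14 adjusted over the list alone; camera adjusted p = 5.64e-16, and adjusted p = 0.0164 with an estimated correlation), among them H1-2 by log2 3.76 and H2BC5 by 3.57. Of 17 immediate early genes, 12 rose and 4 fell (13 and 4 adjusted over the list alone; camera adjusted p = 1.3e-06, and adjusted p = 0.0197 with an estimated correlation), with JUNB up by log2 2.69 and MYC down (log2 -1.31). Of 18 p53 targets, 11 rose and 2 fell (11 and 2 adjusted over the list alone; camera adjusted p = 0.00186), a set call lost with an estimated correlation (adjusted p = 0.0833). Changed genes numbered 9972, of which 5207 were higher and 4765 lower, and 2711 and 820 were at least 2-fold.

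The HBB guide was compared with the non-targeting guide, both with VPRP. Beside HBB, DMBT1, a mucosal glycoprotein, was 54.2-fold higher (log2 5.76, SE 0.316, adjusted p = 3.59e-16), EVPL 40.2-fold, MYO1A, a brush-border myosin, 35.5-fold, COL16A1, a collagen, 21.2-fold, SV2A, a synaptic vesicle protein, 20.8-fold and NCAM2, an adhesion molecule, 16.4-fold. TWIST2 had a count ratio of 120 (95% interval 21.1 to 4770). MAGEA10 was 148-fold lower, LINC01419 34.9-fold, LINC00470 29.9-fold, GABRA3 28.4-fold, GDA 27.7-fold, MKRN3 24.0-fold, WDR72 21.7-fold and CHRM3 20.8-fold. The comparison crosses the MAGEA10 split, and EP300 reads were 3.13-fold lower with the HBB guide (log2 -1.65, SE 0.082, adjusted p = 2.74e-17). Whether the guide caused these differences was not tested, so its effects cannot be told apart from them. Of 15 replication-dependent histone genes, 13 fell (13 adjusted over the list alone; camera adjusted p = 2.05e-16, and adjusted p = 0.0164 with an estimated correlation), H2AC6 by log2 -1.89 and H1-2 by -1.30. Of 17 immediate early genes, 12 fell (12, with 1 higher, adjusted over the list alone; camera adjusted p = 9.22e-09, and adjusted p = 0.0164 with an estimated correlation). Among the p53 targets (18 tested), 14 rose and 3 fell (14 and 3 adjusted over the list alone; camera adjusted p = 6.86e-08, and adjusted p = 0.0164 with an estimated correlation). There were 2491 higher and 2407 lower genes (2369 and 2507 with RLE factors), 336 and 628 of them at least 2-fold; the total of 4898 became 3185 without VPRP non-target replicate 1 and 3200 without replicate 2.

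**Figure D3:**
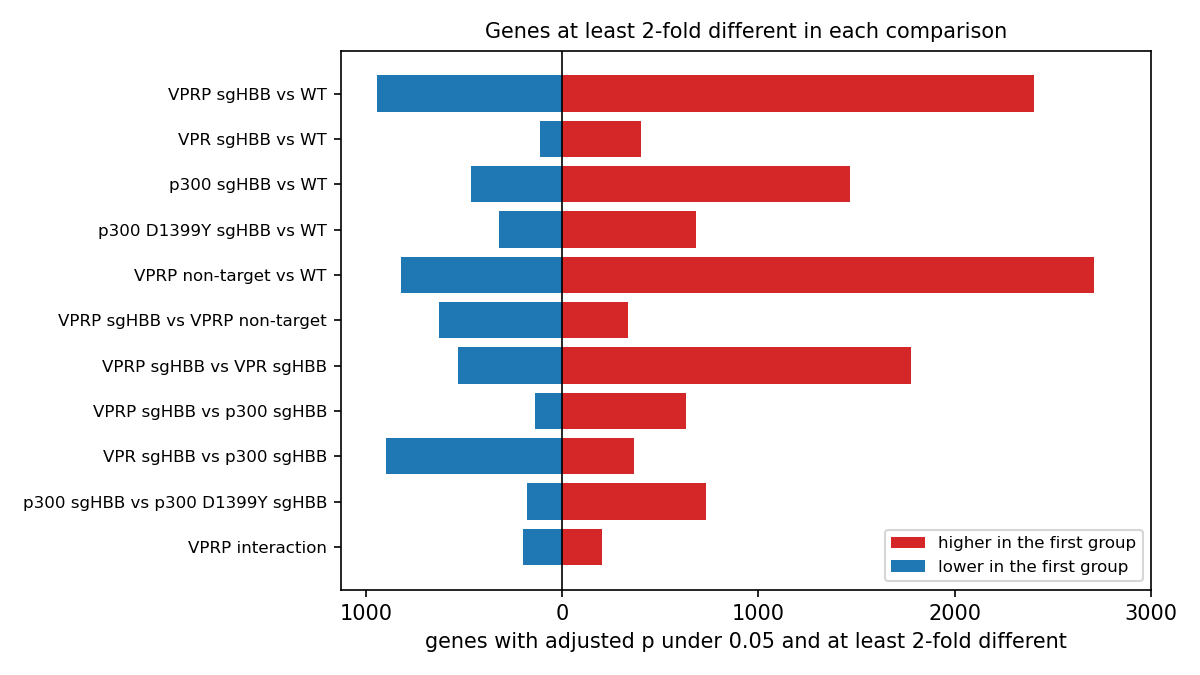
Number of genes with adjusted p under 0.05 and at least 2-fold different in each comparison (edgeR); bars to the right are higher and bars to the left lower in the first-named group, and for the interaction they are positive and negative. VPRP non-target against WT has 2711 higher genes and VPR against WT 404.

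VPRP was compared with VPR, with the same guide, to show what the p300 part added; the pair crosses the MAGEA10 split. FRG2 was at least 124-fold, LINC01647 at least 59.4-fold, GOLGA6FP at least 40.3-fold, TWIST2 at least 35.2-fold and RRAD at least 33.3-fold higher. RFPL4A had a count ratio of 1130 (95% interval 202 to 44500), FRG2B of 765 (137 to 30200) and FRG2C of 599 (166 to 4950). MAGEA10 was 119-fold lower, LINC00470 42.5-fold, GDA 39.9-fold, WDR72 35.5-fold, GABRA3 30.9-fold, MKRN3 26.0-fold, FLI1 23.5-fold and CHRM3 17.8-fold. Of 17 immediate early genes, 12 rose and 3 fell (12 and 3 adjusted over the list alone; camera adjusted p = 0.000155, and adjusted p = 0.0414 with an estimated correlation), with EGR1 up by log2 4.61 and FOS by 2.98. Genes higher numbered 4118 and genes lower 4189, and 1779 and 530 were at least 2-fold.

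VPRP was also compared with p300, both with the HBB guide and on the same side of the MAGEA10 split, to show what the VPR part added. DMBT1 was 33.6-fold higher (log2 5.07, SE 0.294, adjusted p = 2.32e-15), AEBP1, a transcriptional repressor, was higher by log2 4.40, and MPO had a count ratio of 82.2 (95% interval 22.4 to 685). MAGEA10 was called higher (at least 2.33-fold, adjusted p = 0.0156), a call lost without VPRP sgHBB replicate 1 (adjusted p = 0.069), p300 replicate 1 (0.0844) or p300 replicate 2 (0.0881). ATF3, a stress-response transcription factor, was 7.18-fold lower, the histone gene H2AC6 3.82-fold, SLC6A9 3.66-fold and OVGP1, an oviductal glycoprotein, 3.55-fold. In the p53 list of 18 targets, 13 rose and 1 fell (13 and 1 adjusted over the list alone; camera adjusted p = 2.43e-07, and adjusted p = 0.0164 with an estimated correlation). EP300 reads were lower with VPRP (log2 -1.59, SE 0.082, adjusted p = 1.37e-16). The counts were 2380 higher and 2280 lower genes, 631 and 140 of them at least 2-fold, and the total of 4660 became 3089 without p300 replicate 1.

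VPR and p300 were compared directly, across the MAGEA10 split. MAGEA10 was at least 288-fold higher with VPR, and the count ratios were 84.9 for MPO (95% interval 23.1 to 708) and 73.8 for LINC00470 (24.9 to 361). With VPR, TWIST2 was at least 40.8-fold, RRAD at least 21.6-fold and FRG2 at least 18.2-fold lower, and MIR7-3HG had a count ratio of 0.00205 (5.19e-05 to 0.0115). Of 17 immediate early genes, 11 were lower with VPR (11 adjusted over the list alone; camera adjusted p = 5.49e-14, and adjusted p = 0.00846 with an estimated correlation), and so were 9 of 15 replication-dependent histone genes (10 adjusted over the list alone; camera adjusted p = 1.36e-09, and adjusted p = 0.0414 with an estimated correlation). In total 2846 genes were higher and 2878 lower with VPR, 365 and 897 of them at least 2-fold.

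The last pair, p300 against p300 D1399Y with the HBB guide, addressed the catalytic activity; both lie on the same side of the MAGEA10 split, and EP300 reads were 5.78-fold higher with p300 (log2 2.53, SE 0.085, adjusted p = 2.95e-22). DHRS2, a dehydrogenase, was 91.2-fold higher (log2 6.51, SE 0.135, adjusted p = 1.17e-28), and SCIRT, a long non-coding RNA, 45.1-fold. MIR7-3HG was at least 170-fold and GOLGA6FP at least 18.4-fold higher. Count ratios were 119 for FRG2B (95% interval 21 to 4740), 95.3 for FRG2C (16.7 to 3800), 70.5 for RFPL4A (23.8 to 345) and 55.3 for PRR20G (9.54 to 2220). MPO had a ratio of 0.0116 (0.0014 to 0.0427), and EVPL was 7.01-fold, DMBT1 5.73-fold, AEBP1 4.30-fold, IGFBP5, which binds insulin-like growth factors, 3.78-fold, PPL, a desmosomal protein, 3.45-fold, HOXB5, a homeobox transcription factor, 3.31-fold and CEL, a lipase, 3.13-fold lower. Of 23 genes of the integrated stress and unfolded protein responses, 11 rose (12 adjusted over the list alone; camera adjusted p = 2.16e-12, and adjusted p = 0.0424 with an estimated correlation), ATF3 by log2 3.63 and DDIT3 by 3.27. Of 17 immediate early genes, 10 rose (10 adjusted over the list alone; camera adjusted p = 1.2e-12, and adjusted p = 0.0119 with an estimated correlation), and of 15 replication-dependent histone genes, 9 rose (9 adjusted over the list alone; camera adjusted p = 2.27e-11, and adjusted p = 0.0351 with an estimated correlation). Of 18 p53 targets, 15 fell and 1 rose (16 and 1 adjusted over the list alone; camera adjusted p = 1.09e-10, and adjusted p = 0.0119 with an estimated correlation), BAX by log2 -0.82 and CDKN1A by -0.65. Genes higher numbered 2575 and genes lower 2501, with 735 and 178 at least 2-fold; the total of 5076 became 3226 without p300 replicate 1 and 3193 without p300 D1399Y replicate 1.

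The 735 genes at least 2-fold higher with p300 than with p300 D1399Y were followed in comparisons that share no library with that pair. In VPRP non-target against WT their median was log2 2.47, with 622 higher and 4 lower, while 10000 random gene sets matched on mean expression had medians around 0.33 (95% range 0.24 to 0.42). In VPRP sgHBB against VPR sgHBB, which crosses the MAGEA10 split, their median was log2 1.80, with 540 higher and 18 lower (random sets 0.18, range 0.11 to 0.25). It was 2.18 in VPRP sgHBB against WT, also across the split (572 higher, 19 lower), and 0.27 in VPR against WT (111 higher, 17 lower), both without random sets. In VPRP sgHBB against VPRP non-target it was -0.35 (221 lower, 59 higher), taken up at the end. These medians are of fitted values, which for genes near 0 counts depend on the prior count.

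The VPRP interaction asked whether adding VPR changed a gene differently with and without p300. RASD1, a small GTPase, had an interaction of log2 4.41 (SE 0.597, adjusted p = 3.98e-06) and PCDH8, a protocadherin, of 3.34 (SE 0.55, adjusted p = 6.67e-05); MYD88, an adaptor of innate immune receptors, had one of -2.94 (SE 0.472, adjusted p = 5.01e-05) and EDA2R, a receptor of the TNF family, of -2.75 (SE 0.42, adjusted p = 2.43e-05). RASD1 was at 0.663 ± 0.298 CPM in WT, 0.295 ± 0.0304 with VPR, 1.62 ± 0.38 with p300 and 15.8 ± 1.22 with VPRP. MYD88 was at 0.263 ± 0.0861 CPM in WT, 2.47 ± 0.00456 with VPR, 6.70 ± 0.224 with p300 and 7.98 ± 0.428 with VPRP. Of 25 cell cycle genes, 15 had a negative interaction (15 adjusted over the list alone; camera adjusted p = 6.46e-13), a set call lost with an estimated correlation (adjusted p = 0.0705). The interaction passed for 2539 genes, 1115 positive and 1424 negative, 205 and 198 of them at least 2-fold. With RLE factors it passed for 1280 positive and 1141 negative genes, so which sign prevailed turned with the scaling. The total became 1427 without p300 replicate 1 and 1619 without WT replicate 2. The 4 groups of this test lie on different sides of the MAGEA10 split. Each side enters once with a plus and once with a minus sign, so an equal log2 shift cancels.

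The other gene lists were tested in the same way, and none of them kept a set call in any of the 11 comparisons once the correlation was estimated. The p300, p300 D1399Y and VPRP sgHBB comparisons with WT in this paragraph cross the MAGEA10 split. The closest was the heat shock response with VPR, where 8 of 14 genes were higher than in WT (10 and 1 lower adjusted over the list alone; camera adjusted p = 2.84e-06, and adjusted p = 0.0509 with an estimated correlation). Of 15 interferon-stimulated genes, 10 were higher and 1 lower with p300 than in WT (10 and 1 adjusted over the list alone; camera adjusted p = 0.00294, and adjusted p = 0.0833 with an estimated correlation); with VPRP sgHBB, IFI6 was up by log2 3.37 and IFIT1 by 2.31. Blood cell markers were higher in 8 of 11 with VPRP non-target (8 adjusted over the list alone; camera adjusted p = 0.000456, and adjusted p = 0.186 with an estimated correlation), and CORO1A, an actin regulator of leukocytes, was up by log2 3.99 with VPRP sgHBB. Of 22 cholesterol biosynthesis genes, 10 were higher and 2 lower with p300 than with p300 D1399Y (13 and 2 adjusted over the list alone; camera adjusted p = 0.000878, and adjusted p = 0.185 with an estimated correlation). Acetyltransferase, deacetylase and bromodomain genes were 1 higher and 10 lower of 24 with VPR than in WT (1 and 10 adjusted over the list alone; camera adjusted p = 0.000878, and adjusted p = 0.163 with an estimated correlation). Mitochondrially encoded genes were 11 of 13 higher with VPR than in WT (12 adjusted over the list alone, camera adjusted p = 1.05e-05, and adjusted p = 0.419 with an estimated correlation), with 3.41% of counts in VPR replicate 1 and 2.14% in replicate 2, against 2.1% and 1.88% in WT. Their share was 2.7% to 3.44% in the libraries of the other groups. The list was also called higher than in WT with VPRP sgHBB (camera adjusted p = 0.0162), p300 (0.0018) and p300 D1399Y (2.38e-05). Further, 3 of 5 erythroid markers were higher with p300 D1399Y than in WT (3 adjusted over the list alone; camera adjusted p = 0.0086, and adjusted p = 0.209 with an estimated correlation). Lists of NF-kB targets, glycolysis and hypoxia genes, fibroblast markers, neuronal markers and housekeeping genes had no camera call in any comparison.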

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

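For 2539 genes the change from adding the VPR part differed between cells without and with the p300 part, by the interaction test of edgeR (adjusted p under 0.05). Among the named genes the interaction was log2 4.41 for RASD1, 3.34 for PCDH8, 2.88 for NEFH and 2.78 for HYAL1. It was at most -6.61 for HBB (-5.64 and -5.58 without WT replicate 1 or 2), -2.94 for MYD88, -2.75 for EDA2R, -2.64 for ALDH1A1 and -1.48 for EP300. The negative sign for HBB was close to fixed by the 0 counts in WT. NEFH lost its call without WT replicate 1 (2.27, adjusted p = 0.104) and HYAL1 without WT replicate 2 (2.09, adjusted p = 0.27). The 4 groups of this test differ in EP300 reads, and no group separates these from the fusion. They also differ in MAGEA10, but an equal log2 shift across that split cancels in the interaction. Of the 79 genes at least 8-fold lower with p300 D1399Y than in WT, 3 had a positive and 1 a negative interaction (median log2 0.75). The WT libraries are shared with that choice. Whether cells on the 2 sides respond differently to the fusions was not tested.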

How the results depend on the processing

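Each result was recomputed with DESeq2, RLE or upper-quartile factors, no low-count filter, a stricter filter, fits of the compared groups alone, a replicate block and each of the 12 libraries left out, where the lone library of a group is assumed to vary like the others. Of 402 alternative values of the main results, 390 kept their direction and call, or stayed within 1.5 times a count. Leaving out a library gave 10 of the 12 changes. Many of the 402 values left out a library that was in neither compared group, so the share kept is a mild test. The 69 list calls of 187 tests became 19 with an estimated correlation, and the cause was not tested. The estimate was under the preset 0.01 for p53 targets in VPRP non-target against WT (0.005) and interferon-stimulated genes in p300 against WT (-0.049). Both lost their call, which argues against a higher correlation as the cause for these lists. Other estimates were higher, such as 0.859 for mitochondrially encoded genes in VPR against WT. With fry 116 of the 187 tests were called, which is another question, since fry tests a list against no change and camera against the other genes. Without 1 library, changed genes ran from 2548 to 4367 for VPR against WT, 3185 to 5438 for VPRP sgHBB against VPRP non-target, 3089 to 5227 for VPRP against p300, 3193 to 5623 for p300 against p300 D1399Y and 1427 to 3278 for the interaction. The highest counts of VPRP sgHBB against VPRP non-target, VPRP against p300 and p300 against p300 D1399Y came without a VPR library, which is in neither group. All groups share the estimate of the spread, and the VPR libraries varied most (13.67 times the Poisson value). The cause of the rises and falls was not tested. The share of higher among changed genes stayed within 10 points, but which direction held more genes turned in 6 comparisons. VPR against WT (54.7% higher) had 49.1% with RLE factors, 48.7% with DESeq2, 49.7% with the compared groups alone and 61% with upper-quartile factors. p300 D1399Y against WT (52.1%) had 48.4% with RLE factors, 48.3% with DESeq2 and 48.7% with no filter, and the interaction (43.9% positive) had 52.9% with RLE factors, 53.3% with DESeq2 and 36.4% with upper-quartile factors. The others were VPRP sgHBB against VPRP non-target (50.9%, then 48.6% with RLE factors), VPRP against VPR (49.6%, then 53.4% with the compared groups alone) and p300 against p300 D1399Y (50.7%, then 49.8% with DESeq2 and 59.5% with upper-quartile factors). Of 16091 values of named genes, 15684 kept direction and call, 359 lost the call, 2 gained one and 46 changed sign, all in genes with no call in the reported fit. No value was given for 33 under the stricter filter, 29 with only the compared groups and 16 with DESeq2.

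Pairing libraries by number as a replicate block left 69 list calls and 9724 changed genes in VPRP against WT, against 9868, and no count moved over 1.5 times. The difference in log2 CPM between replicates 1 and 2 was close to uncorrelated between groups. Over the 15 pairs of groups the correlations ran from -0.041 to 0.066, all below the threshold of 0.1.

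Changed signs, the cause not tested, were HBQ1 in the interaction (0.025 with RLE, 0.01 with the compared groups alone, 0.023 with DESeq2), HBQ1 in p300 against WT (0.017 with upper-quartile factors) and HBG2 in VPRP non-target against WT (-0.008 with no filter). Leave-one-out ranges of log2 values that changed sign were, for HBQ1, -0.118 to 0.105 (interaction), -0.153 to 0.071 (p300 against WT) and -0.147 to 0.044 (VPRP against VPR). For HBG2 they were -0.353 to 0.555 (VPRP non-target against WT), -0.165 to 0.742 (VPR against WT), -4.73 to 1.593 (p300 against WT), -0.734 to 1.233 (p300 D1399Y against WT), -1.382 to 4.942 (VPR against p300), -5.259 to 1.327 (p300 against p300 D1399Y) and -0.176 to 6.148 (interaction). For HBA2 they were -2.409 to 4.143 (p300 D1399Y against WT), -0.852 to 0.294 (VPRP sgHBB against VPRP non-target), -2.059 to 3.144 (p300 against p300 D1399Y) and -0.802 to 2.486 (interaction), and for HBA1 -4.06 to 0.176 (VPR against p300) and -0.626 to 0.964 (p300 against p300 D1399Y). For HBE1 they were -0.113 to 0.034 (VPRP sgHBB against VPRP non-target), -0.211 to 0.151 (VPRP against p300) and -1.037 to 3.757 (interaction). For RELA they were -0.141 to 0.01 (VPRP against VPR), -0.137 to 0.014 (VPR against p300) and -0.133 to 0 (p300 against p300 D1399Y). EP300 in VPR against WT ran from -0.306 (without VPR replicate 1, adjusted p = 0.00697) to 0.063. HBG2 in VPRP against p300 was called without p300 replicate 1 (6.36, adjusted p = 0.0273).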

Other observations

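Gene families defined by symbol gave further changes; the 6 families (HOX, MAGE, clustered protocadherin, ZNF, keratin, and GOLGA6 and GOLGA8 genes) were chosen after the comparisons were seen, and their 66 camera tests were adjusted together. Of 35 HOX genes, regulators of body axis identity, 30 were lower with p300 than with p300 D1399Y (median log2 -0.84; adjusted p = 1.88e-19, and adjusted p = 0.00588 with an estimated correlation). In VPRP non-target against WT, which shares no library with that pair, 26 were lower and 5 higher (median log2 -0.83; adjusted p = 8.68e-06, and adjusted p = 0.0277 with an estimated correlation). With VPR against WT 6 were higher and 6 lower (adjusted p = 0.871). Of 18 MAGE genes, cancer-testis antigens, 16 were higher and 1 lower with VPRP non-target than in WT (median log2 2.39; adjusted p = 6.46e-05, and adjusted p = 0.0245 with an estimated correlation). In VPR against WT 7 were higher (adjusted p = 4.87e-05, and adjusted p = 0.0245 with an estimated correlation), and in VPRP sgHBB against p300 7 were higher (adjusted p = 0.000426, and adjusted p = 0.0324 with an estimated correlation). In comparisons that cross the MAGEA10 split, which 5 of these genes help define, they were lower in VPRP sgHBB against VPRP non-target (9 lower, 3 higher, median log2 -1.52, adjusted p = 1.03e-11, and adjusted p = 0.0122 with an estimated correlation). That comparison shares its VPRP non-target libraries with the rise. In p300 D1399Y against WT 5 were lower and 3 higher (median log2 -0.23, adjusted p = 1.49e-05, and adjusted p = 0.0226 with an estimated correlation). The 5 lower genes are those of the split, picked in that same comparison, so that result is no separate evidence. No call was made in VPRP sgHBB against WT (adjusted p = 0.936), p300 against WT (0.0625) or VPRP sgHBB against VPR (0.0867). With VPR against p300, which also crosses the split, 5 were higher and 3 lower (adjusted p = 5.67e-08, and adjusted p = 0.0135 with an estimated correlation). This call cannot be told apart from the split, which 5 MAGE genes help define. Of 23 GOLGA6 and GOLGA8 genes, which are near-identical copies, 21 were higher in VPRP non-target against WT (adjusted p = 1.65e-06), a call lost with an estimated correlation (adjusted p = 0.0551). Of 451 ZNF genes, 127 were lower and 16 higher with VPRP sgHBB than with VPRP non-target, across the MAGEA10 split (adjusted p = 1.49e-05, and adjusted p = 0.0562 with an estimated correlation). Clustered protocadherins had no call in any of the 11 comparisons, and the keratins had 1, for p300 D1399Y against WT, across the split (3 of 9 higher, adjusted p = 0.0369, and adjusted p = 0.243 with an estimated correlation).

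Genes without a read in either WT library and at 1 CPM or more in both libraries of a group numbered 72 with VPRP non-target, 41 with VPRP sgHBB, 18 with p300, 11 with p300 D1399Y and 3 with VPR; those of VPRP sgHBB, p300 and p300 D1399Y cross the MAGEA10 split. The reverse, at 1 CPM or more in both WT libraries and without a read in the group, held for 0, 2, 3, 5 and 1 genes.

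The split of MAGEA10 and other genes across the groups was weighed against 3 explanations, in tests chosen after values of the split had been seen. The 79 genes at least 8-fold lower with p300 D1399Y than in WT had a median of log2 -2.82 in VPRP sgHBB against VPRP non-target (quartiles -4.46 and -1.84, 61 lower), groups with the same fusion, at different EP300 read levels, and no library in common with the choice, which argues against activity of the fusion as the cause. Their median in VPR against p300, which carry the same guide, was log2 3.6 (quartiles 1.68 and 4.93), again with no library in common with the choice, which argues against the guide alone, since that would leave VPR and p300 within log2 1 of each other. The share called higher in VPR against p300, 58 of 79 (73.4%), fell short of the bound written for it, while in the 20 genes with mean log2 CPM of at least 1, a filter chosen after values had been seen, 20 were higher (median 3.95). Acetyltransferase fusions acting together with the HBB guide predict the split itself (median log2 -3.6 in p300 against WT), so the groups at hand cannot separate them from a difference between cell populations. The split was also present with p300 D1399Y, whose catalysis is impaired and whose EP300 excess was 8.66% of that in p300. This argues against a joint action that needs full catalysis or a large EP300 excess. How deep the falls went cannot be compared, since the genes were picked in p300 D1399Y.

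The genes higher with p300 than with p300 D1399Y were weighed against the amount of EP300 reads, with 1 of the 2 predictions written after the values were seen, that on the 178 genes. In VPRP sgHBB against VPRP non-target, which differ in EP300 reads, the 735 genes had a median of log2 -0.35 (221 lower, 59 higher; 10000 random sets matched on expression gave -0.09, range -0.14 to -0.04). The direction fits an effect of the amount of the fusion transcript, though the comparison also crosses the MAGEA10 split and differs in guide. The 178 genes at least 2-fold lower with p300, against 735 higher, cannot tell amount from catalysis.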
